A study of Mus musculus with 10 samples.

How the data were processed

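DNA of mouse embryos at embryonic day 7.5 was purified with phenol-chloroform and made into reduced representation bisulfite libraries with a commercial kit, per the labels' protocols. The submitters' processing notes name Trim Galore, Bismark, methylKit and the genome build mm10. Versions and settings of these tools are not given in the sources used here. The deposited table holds raw counts, 3 per library and cytosine position, which are the reads covering the position, those calling it methylated and those calling it unmethylated, per the file headers. Both call counts added up to the coverage at each position, each position was covered by at least 10 reads in each library, and both strands were listed separately, as tested on the table. The values are whole numbers with unequal totals per library and were used without normalization. The table holds only positions covered in each library, so the values describe the shared part of the libraries. No source used here names molecular identifiers, and intervals cover counting error only. At gene ends they take each call as independent, which makes them too narrow where a read covers several positions.

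The 10 sets of count columns carry the numbers 1 to 10, whereas the sample titles are control 1 to 5 and arsenic 1 to 5. A column was to be given a sample only where its name matches that sample alone, and 0 of the 10 columns met this. The order of columns was not used. The comparison of arsenic with control planned before the data were examined, by logistic models of single positions, tiles and promoters and by permutation tests of group means, was not run. The values over the 10 columns are given as median and range, as planned for this case, with no mean over replicates and no test between groups. That the columns are the 10 samples of the series rests on their number and on the table being deposited with it.

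Of 2137826 rows, 2 repeated a position with a different count in 1 column and were left out. The methylation level is the number of methylated calls divided by coverage, in percent. Means over positions weight each position equally, and levels of gene ends are sums of methylated calls over sums of coverage. X and Y were kept out of the autosomal values. Gene positions came from a RefSeq gene table of the assembly that mm10 corresponds to, GRCm38, without strand or exons. The promoters, exons and introns of the plan were therefore replaced by windows of 1000 bp on each side of a gene end, by the inside of genes and by the rest. The local number of measured positions within 100 bp replaced CpG density, and repeats were not analysed. For each gene the end with more measured positions was used, with at least 3 positions. Overlapping genes can share a window. Of 349 gene names in 12 lists fixed before the data were examined, 347 were matched, 1 of the others being a second name of a listed gene. The rule for genes to be named rested on p-values and could not be used. The genes named are mainly those with the highest and lowest levels of each list, any imprinted gene, and well-known members, chosen after the values were seen. The stand-in for promoters was also set once the gene table was known.

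Each list's median was set against 10000 random lists of gene ends, coding and non-coding, drawn from the same of 10 bins of the number of measured positions. This percentile describes the summed libraries and is not a test across replicates. It was also computed with genes that share the same positions counted once, and against lists of protein-coding gene ends alone, steps added after the values were seen. The spread between columns at the 23435 gene ends was measured as the chi-square per degree of freedom of methylated against unmethylated calls. Calls of the same read at neighbouring positions are not independent and raise this value. It therefore serves only to set gene ends against each other, and no count of differing gene ends is given. The size of this effect can differ between gene ends and was not measured. On random lists, 5.50% had a percentile outside the central 95%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used. Alternatives covered the coverage minimum, removal of the most covered positions, the X chromosome, weighting by coverage, the window and choice of gene ends, the number of positions and leaving out each column.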

Results

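Reduced representation bisulfite sequencing measures cytosine methylation in the CpG-rich part of the genome, where a restriction enzyme frees short fragments and unmethylated cytosines are read as thymines after bisulfite treatment. The series holds 10 samples of mouse embryos at embryonic day 7.5, when gastrulation is under way. The titles place 5 samples in a control group and 5 in an arsenic group, and the series states that the study compared DNA methylation between these groups. The deposited table gives 10 sets of read counts that carry only the numbers 1 to 10. None of these numbers names a group, and the numbers 1 to 5 occur in a control title and in an arsenic title alike. No set of counts was therefore tied to a sample or a group, and no comparison of arsenic with control was made. Each set is called a library column here, values are given over the 10 columns as the median and range, and any difference between the groups is contained in that range without being visible as such.

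The table covered 2137824 cytosine positions on the 19 autosomes and on X and Y, of which 2101419 were autosomal. Each position had at least 10 reads in each of the 10 columns. The coverage summed over these positions, in which a read counts once for each position it covers, ranged from 73509873 in column 3 to 127743904 in column 1, and the median coverage of an autosomal position ranged from 26 to 48 reads. Levels at the 2 strands of the same CpG, available for 647386 autosomal CpGs, averaged 38.2% on both strands and had a median absolute difference of 2.29 percentage points. Pearson's r of the levels between library columns, across positions and not across independent replicates, lay between 0.887 and 0.927 over the 45 pairs.

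Methylation in these embryos was split between a nearly unmethylated and a partly to highly methylated part of the measured genome. With the reads of all columns summed, 30.8% of autosomal positions were methylated at under 10%, and a broad second group was centred on levels of 60 to 70%, which held 13.4% of positions. Levels above 90% were found at 1.90% of positions. The mean level of an autosomal position was 41.1% as the median over the columns, with a range from 40.1% to 42.7%.

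**Figure D1:**
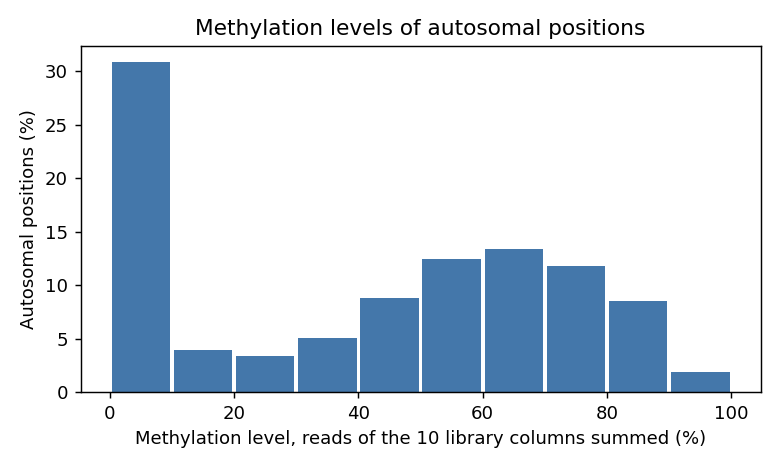
The x axis gives the methylation level of an autosomal position in %, from the summed reads of the 10 library columns, and the y axis the share of positions in %. The bar from 0 to 10% holds 30.8% of positions and the bar from 60 to 70% holds 13.4%.

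Gene ends were far less methylated than the inside of genes and the space between them. Positions within 1000 bp of either end of a protein-coding gene had a mean level of 10.3%, with a range over the columns from 10.1% to 10.7%, and 84.8% of them were methylated at under 20%. Positions inside protein-coding genes but away from their ends had a mean level of 51.6%, with a range from 50.5% to 53.5%, and those outside protein-coding genes 52.8%, with a range from 51.3% to 55.3%. The order of the last pair reversed when positions were weighted by coverage, to 52.6% inside and 50.7% outside genes, and with windows of 2000 bp, to 55.4% and 53.4%. The columns of the gene-end class did not overlap those of the other classes. Levels also fell with the local density of measured positions. They were 56.2% where at most 5 positions lay within 100 bp, the position itself included, 46.6% with 6 to 15 positions and 12.6% with more than 15 positions. Across autosomes, the median level ranged from 36.6% on chromosome 11 to 43.5% on chromosome 10. Positions on X had a median level of 48.5% with a range from 47.3% to 49.9%, and positions on Y 60.4% with a range from 58.0% to 63.7%.

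**Figure D2:**
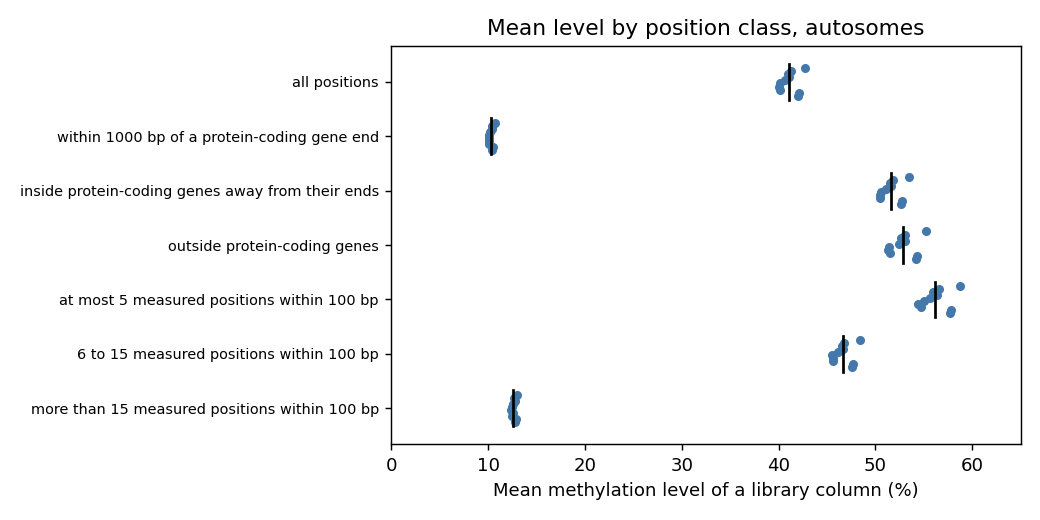
The x axis gives the mean methylation level in %, and each row is a class of autosomal positions. Each point is 1 of the 10 library columns and the vertical line is their median. Gene ends and densely measured positions lie at 10.3% and 12.6%, and the other classes between 41.1% and 56.2%.

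The methylation of single genes was measured within 1000 bp of the gene end that had more measured positions, since the gene table used gives no strand. This end is a stand-in for the promoter and can be the 3' end. Whether the end used is the 5' or the 3' end is not given by that gene table for any gene, however many positions were measured. Of 14236 autosomal protein-coding genes with at least 3 such positions, 75.6% had a level under 20%, 23.1% a level between 20 and 80%, and 1.29% a level above 80%. The values of single genes below are levels over the summed calls with their 95% Wilson interval and the range over the 10 columns. A read that spans several positions gives several calls, which are not independent, so these intervals are too narrow even for counting error.

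Gene ends of imprinted genes, in which methylation is set on 1 parental allele, lay mostly at intermediate levels. Of 29 measured genes of the list, 22 had a level between 20 and 80%, 7 were under 20% and none was above 80%. The list's median gene level was 45.1%, against 6.93% for random lists matched on the number of measured positions, and it lay above 9986 of 10000 such lists. These lists, here and for the other sets of genes, were drawn from all gene ends, of which 14236 of 23435 are protein-coding, and percentiles among protein-coding gene ends are given beside them. With genes that share the same positions counted once, 28 regions had a median of 44.6%, above 9962 of 10000 lists. The 22 protein-coding genes of the list had a median of 44.0%, above all 10000 lists of protein-coding gene ends. Between 40 and 65%, limits set after the levels were seen, lay 17 of the 29 genes, or 58.6%, and 23.0% of all autosomal gene ends. The mean levels of positions inside and outside protein-coding genes, 51.6% and 52.8%, lay in this interval too. Parental alleles were not told apart, so a level in it need not mean methylation of 1 allele. Airn, a non-coding RNA antisense to Igf2r, had a level of 51.7% (95% interval 50.9 to 52.4%, 16236 calls, range 40.2 to 58.1%) on chromosome 17 from 12740311 to 12742311 (mm10). The end of Igf2r itself, on chromosome 17 from 12768706 to 12770706, had a level of 13.5% (interval 12.9 to 14.1%). Kcnq1ot1, the antisense RNA of the Kcnq1 locus, had 45.5% (interval 44.1 to 46.9%, range 28.4 to 65.2%), and Plagl1, a zinc finger gene, 49.1% (interval 48.0 to 50.3%, range 33.9 to 74.0%). H19 had a level of 47.1% with a range from 37.0% to 58.4%, and its neighbour Igf2 54.3% over only 3 positions. Peg10 and Sgce share the measured region on chromosome 6, whose level was 53.7% with a range from 41.3% to 68.1%. Nnat had the highest level of the list at 62.3%, with a range from 56.1% to 70.6%. The lowest levels were those of Trappc9 at 1.61%, Dlk1 at 1.78%, Grb10 at 3.10% and Inpp5f at 3.89%, each measured at an end of the gene that need not hold its differentially methylated region.

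Genes of the germ line had the highest gene-end methylation of the lists examined. Of 27 measured genes, 24 lay between 20 and 80%, 1 above 80% and 2 under 20%. The median gene level was 56.2%, against 6.50% for matched random lists, above all 10000 of them, and above 9999 with shared regions counted once. It also lay above all 10000 lists of protein-coding gene ends, whose median was 3.79%. Over the columns the mean of the list ranged from 48.4% to 54.1%. Mov10l1, which takes part in the piRNA pathway, had a level of 73.0% (interval 72.0 to 74.0%, range 65.8 to 78.8%). Dpep3 had the highest level at 85.4%, over 4 positions, with a range from 78.1% to 96.4%. The meiotic chromosome genes Sycp1 and Sycp3 had 48.7% and 52.8%. Dazl, an RNA-binding protein of germ cells, was measured over 130 positions at 37.8% (interval 37.4 to 38.2%, range 32.4 to 43.8%), on chromosome 17 from 50292620 to 50294620. The cohesin genes Stag3 and Smc1b had the lowest levels of the list, 11.2% and 16.9%.

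Genes of arsenic metabolism and the oxidative stress response were mostly unmethylated at the measured end. Of 21 measured genes, 17 were under 20% and 4 between 20 and 80%. Their median gene level of 1.35%, against 2.90% in matched random lists, lay at percentile 3.20, and at percentile 6.85 among lists of protein-coding gene ends, whose median was 2.26%. The mean over genes was 10.7% and rose to 22.2% with windows of 2000 bp, in which 15 of 26 measured genes were under 20% and the median was 4.63%, at percentile 5.09. Keap1 and Nfe2l2, the sensor and the transcription factor of the antioxidant response, had levels of 0.715% (interval 0.631 to 0.812%, range 0.364 to 1.35%) and 0.743% (interval 0.599 to 0.921%, range 0.282 to 1.25%). The glutathione synthesis genes Gclc and Gclm had 1.36% and 0.951%, and the metallothionein gene Mt2 1.26%. The aquaporin genes had higher levels, with Aqp9 at 69.6% over 20 positions (range 63.3 to 76.9%), Aqp7 at 52.4% over 6 positions and Aqp3 at 36.7% over 7 positions. The end measured can be the 3' end for each of them, so these need not be promoter levels. As3mt, the arsenic methyltransferase, did not reach 3 measured positions at either end.

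One-carbon metabolism, which supplies the methyl group for DNA methylation, had 21 of 22 measured genes under 20%. The median gene level was 1.48%, against 3.54% in matched random lists, at percentile 2.89, and at percentile 6.96 among protein-coding gene ends. With windows of 2000 bp the median was 4.67%, against 8.69% in matched lists, at percentile 12.6. The mean over genes was 6.80%, and 3.92% with at least 5 positions per gene. Mtr, methionine synthase, had 0.632% (interval 0.547 to 0.731%) and Ahcy, which removes S-adenosylhomocysteine, 0.661% (interval 0.568 to 0.770%). Bhmt was the exception at 63.7%, measured at 3 positions, and Cth followed at 16.3%. Of the DNA methylation machinery, 15 of 18 genes were under 20%, and the median of 2.15% lay at percentile 39.5 of matched random lists and 53.2 among protein-coding gene ends. With windows of 2000 bp the median was 4.79%, at percentile 51.0. Trim28 had 0.504% and Tdg 0.549%, Dnmt3b 1.24% with a range from 0.681% to 4.15%, and Tet1 0.938%. Hells at 79.8% over 5 positions and Zfp57 at 79.2% over 7 positions were the highest of that list, and Dnmt3l had 55.0% over 10 positions.

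Genes that pattern the embryo were mostly lowly methylated. Of 36 measured Hox genes, which set position along the body axis, 30 were under 20% and 6 between 20 and 80%. Their median of 8.80% exceeded the 2.74% of matched random lists, above 9973 of 10000 lists and above 9999 of those of protein-coding gene ends. Hoxd4 (interval 37.3 to 38.8%, range 33.3 to 44.9%) and Hoxa5 (interval 36.9 to 39.0%, range 30.5 to 52.3%) were the highest, and Hoxd8 at 0.908% and Hoxb4 at 2.77% the lowest. The end measured can be the 3' end for each of them, so this need not be an order of promoters. Of 31 gastrulation and germ layer genes, 23 were under 20% and 8 between 20 and 80%, with a median of 6.42% at percentile 94.4, and 98.9 among protein-coding gene ends. With windows of 2000 bp the median was 7.67%, against 5.40% in matched lists of all gene ends, at percentile 83.5. Sox2 had 1.18%, Mixl1 1.62% and Eomes, a T-box gene of the primitive streak and trophoblast, 1.73% with a range from 0.619% to 3.85%. Bmp4 was the highest at 71.2% over 37 positions (interval 70.6 to 71.8%, range 65.5 to 76.0%), followed by Cer1 at 66.3% over 7 positions. Both were measured at an end that can be the 3' end. Clustered protocadherin genes, which encode neuronal adhesion molecules, had a median of 33.7%, against 4.51% in random lists, above 9999 of 10000 lists, and 33 protein-coding members lay above all 10000 lists of protein-coding gene ends. Their 34 values came from 22 distinct regions, since many genes of the gamma cluster end at the same point, where the level was 40.5%. This shared level is not that of a separate promoter of each gene. Counted once, the 22 regions had a median of 21.2%, above 9946 of 10000 lists of all gene ends. The 33 protein-coding members were not reduced in this way, so their place rests in part on the shared region. Pcdhb17 had 47.1%, and Pcdhgc3 and Pcdhgc4 had 2.68% and 5.46%.

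Markers of other tissues that a dissected embryo can carry along were examined in the same way, at an end that can be the 3' end. Of 18 trophoblast and extraembryonic ectoderm markers, 15 were under 20%, among them Cdx2 at 0.915% and Fgfr2 at 1.17%, while Esrrb had 70.8% and Gata3 83.1%, the latter over 4 positions. Of 13 visceral endoderm and yolk sac markers, 7 lay between 20 and 80%, with Sparc at 56.7% and Hnf4a at 52.5% as the highest and Lrp2 at 1.38% and Rbp4 at 1.55% as the lowest. Of 9 maternal decidua markers, 8 were under 20%, with Wnt4 at 1.21% and Bmp2 at 1.37% as the lowest, and Esr1 had 40.6% over 6 positions. The mean of this list was 11.9%, and 6.60% at a minimum of 20 reads. With windows of 2000 bp its median gene level was 10.8%. Hoxa10 and Hoxa11 belong to the decidua list and to the Hox list. Of 12 blood and immune cell markers, 10 lay between 20 and 80%, with Csf1r at 75.7% and Runx1 at 75.3% as the highest and Tal1 at 1.58% and Cd34 at 9.92% as the lowest. The median gene levels of these lists, in the order given, were 6.22, 40.9, 6.69 and 42.3%, at percentiles 82.9, 88.6, 88.3 and 67.8 of their matched random lists and at 93.8, 98.1, 94.9 and 95.3 among protein-coding gene ends.

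**Figure D3:**
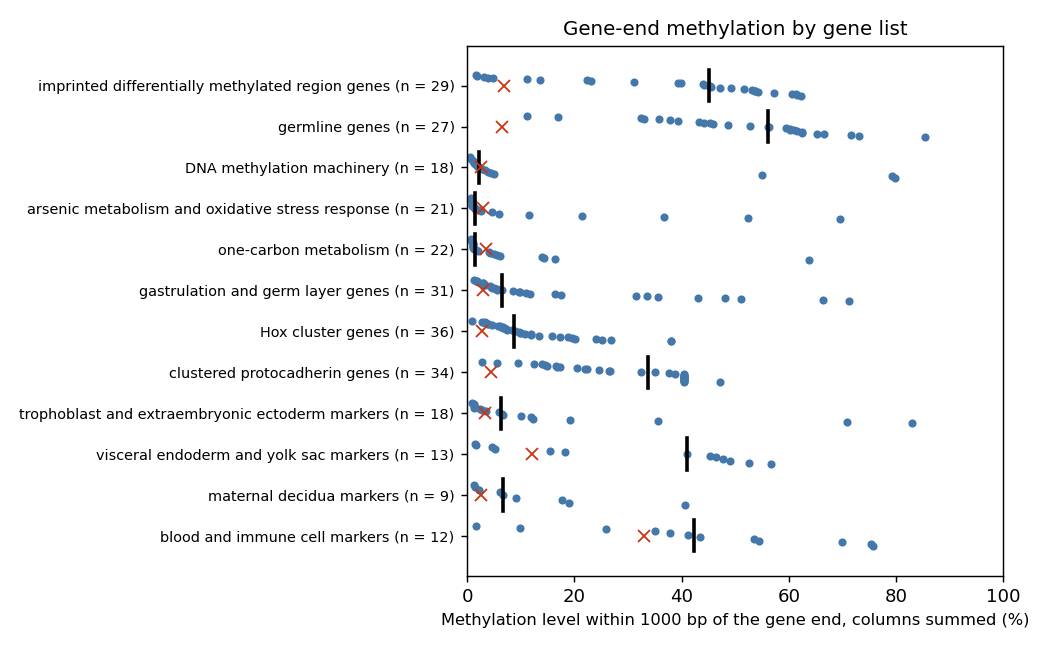
The x axis gives the methylation level within 1000 bp of the gene end in %, from the summed reads of the 10 library columns. Each point is a gene, the vertical line is the median of the list, and the cross is the median of 10000 random lists of all gene ends matched on the number of measured positions. The median of the germline genes is 56.2% and that of the imprinted genes 45.1%, against crosses at 6.50% and 6.93%.

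The sex chromosomes were covered in each of the 10 columns. The median coverage of X positions relative to autosomes ranged from 0.750 to 0.788 in 9 columns and was 0.912 in column 10. Over 327 positions below 3500000 on the Y chromosome, relative coverage ranged from 0.813 to 1.00 in 9 columns and was 0.676 in column 10. The share of summed coverage on all of Y was 0.118% in column 10, within the range of the others, 0.0902 to 0.163%. Mean levels on X within 1000 bp of a protein-coding gene end ranged from 14.6% to 16.9%, the highest in column 10. The labels give no sex of the embryos.

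**Figure D4:**
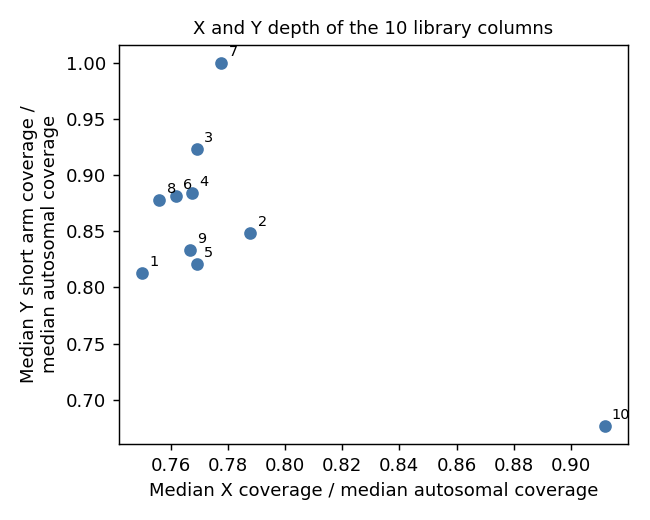
The x axis gives the median coverage of X positions and the y axis that of Y short arm positions, each divided by the median autosomal coverage, with 1 numbered point for each library column. Column 10 lies at 0.912 on x and 0.676 on y, and the other 9 columns at 0.750 to 0.788 on x and 0.813 to 1.00 on y.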

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

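The test on Y reads and the test of a methylation difference on both strands were chosen after the results were seen, and the other tests of this part before, although both patterns they address had been noticed in the table. For the level at densely measured X gene ends no prediction was set beforehand. Of 28 measures examined over the 10 library columns, 4 had a column that lay apart from the other columns by Dixon's test. Both X measures of column 10 are the same observation, and other measures depend on each other too, so the chance rate of about 1 in 20 for a single measure cannot be set against that number. The columns hold 2 groups of samples, and which column belongs to which is not known.

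Library column 10 had 1.35% of its summed coverage on the X chromosome, and the nearest other column 1.18%. Its median X coverage relative to autosomes was 0.912, against 0.750 to 0.788 in the other columns. A few X positions with very many reads are argued against, since the median over X positions, 0.912, is itself apart. A larger share of female cells is a candidate explanation. Relative coverage over 327 positions of the Y short arm was lowest in column 10, at 0.676 against 0.813 to 1.00. The share of summed coverage on all of Y, the measure planned beforehand, does not set column 10 apart. It was 0.118% there and 0.0902 to 0.163% in the other columns. The level at densely measured X gene ends was highest in column 10, at 9.70% against 6.89 to 8.46%. In all columns the relative coverage of the Y short arm is higher than an unpaired chromosome gives relative to paired autosomes. Only positions with at least 10 reads in each column were kept, so this coverage at most ranks the columns and gives no share of male cells. The labels give no sex and no number of embryos per sample, and whether the sexes differ between the control and arsenic groups stays open.

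Library column 9 deviated more from the other columns than its depth accounts for. With each column thinned to 10 reads at 400000 positions of intermediate level, the excess correlation between reads of a position was 0.0666 in column 9 and 0.0296 to 0.0492 in the others, which argues against lower depth as the cause. Few independent molecules behind the reads may account for it, if they were lost on each strand separately. The covariance of deviations between the 2 strands of a CpG, over 216888 CpGs, was 3.04 squared percentage points in column 9. It was 1.13 to 3.80 in the others, so no excess shared by both strands was seen. A shortage of double-stranded DNA at the start could shift both strands alike, so this test does not cover it. A methylation difference of the sample on both strands is argued against as the source: the excess over the highest other column would need a shared variance of 41.4 squared percentage points. A difference between the strands was not tested.

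The mean gene-end level of the arsenic metabolism and oxidative stress list was 9.26% in library column 7, and the nearest other column had 10.1%. Of the 21 genes, 17 lay under 20% over the summed calls, so the mean rests largely on the 4 others. Among these, Aqp7 had only 882 calls over the 10 columns, with a range from 37.0% to 69.0%. Which genes make the gap was not examined, and a shift of the whole list is not shown.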

How the results depend on the processing

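No paired analysis was possible because the columns of the table carry no group, and no column could be tied to a replicate number of either group. For the same reason the planned tests of positions, tiles and promoters, with their alternatives, were not run. Moves below are larger than the counting interval at the median number of calls per column, which is narrow and takes calls as independent, and the order of the classes (all positions, gene ends, inside genes, outside genes, at most 5, 6 to 15 and more than 15 neighbours) is kept in each list. A coverage minimum of 5 moved nothing, since the table starts at 10. A minimum of 20 reads gave 43.0, 11.2, 53.1, 53.3, 57.2, 49.5 and 15.03%. Weighting by coverage gave 42.3, 10.9, 52.6, 50.7, 56.8, 48.1 and 13.7%, so that positions outside genes fell below those inside genes. With X, the values were 41.2, 10.3, 51.6, 53.0, 56.1, 46.6 and 12.7%. Removing the most covered positions gave 52.9% outside genes and moved no other class beyond counting error. Windows of 2000 bp around gene ends, chosen after seeing the data, gave 14.6% at gene ends, 55.4% inside and 53.4% outside genes, which also reversed that order. Leaving out each column in turn, also added later, gave 41.0 to 41.1% for all positions, 10.2 to 10.4% at gene ends, 51.5 to 51.6% inside and 52.7 to 53.0% outside genes, 56.0 to 56.4%, 46.6 to 46.6% and 12.6 to 12.6% for the 3 neighbour classes. Gene ends stayed below the inside and the outside of genes under each of these alternatives. Among the 12 gene lists, whose mean levels over genes were compared, some of the larger moves were those of the arsenic list to 22.2% from 10.7% with 2000 bp windows, of the blood list to 32.95% from 43.4% and the decidua list to 6.60% from 11.9% with at least 20 reads, of the one-carbon list to 3.92% from 6.80% with at least 5 positions, and of the DNA methylation machinery to 2.41% from 13.7% with the median of gene levels. In the leave-one-out results for the lists, 100 of 120 moved by no more than counting error. The cause of the moves was not tested. The shallowest column had a median coverage of 26 reads.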

Other observations

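The gene families, the tests on them and on imprinted genes, and the test of depth were chosen after the table was seen, and the test of conversion before its result was seen. Gene families outside the lists differed widely at the measured end. Percentiles are given among matched random lists of all gene ends and then among those of protein-coding gene ends. Zinc finger genes named Zfp had a median level of 2.18% over 263 genes, below all 10000 lists of all gene ends, whose median was 6.27%, and at percentile 0.11 among protein-coding gene ends, whose median was 3.62%. Of these genes 3 were above 80%. Cytosolic ribosomal protein genes had a median of 1.41% over 65 genes, at percentiles 2.04 and 5.28. Olfactory receptor genes, at 52.0% over 79 genes, lay at percentiles 42.6 and 98.9, so that their place depends on the genes they are set against. Beta-defensin genes, at 49.6% over 11 genes, lay at percentiles 36.0 and 75.9, and keratin-associated protein genes, at 54.0% over 7 genes, at percentiles 52.2 and 85.4. MicroRNA genes, which are not protein-coding, had a median of 54.1% over 418 genes, against 22.3% in lists of all gene ends, above all 10000. With shared regions counted once, 395 regions had a median of 53.7%, against 26.1% in such lists. Both medians lay close to the mean levels of positions inside protein-coding genes, 51.6%, and outside them, 52.8%.

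The chi-square used as a measure of spread between library columns was larger at imprinted gene ends than at other gene ends of like level and depth. For the 17 imprinted genes between 40 and 65%, the chi-square per degree of freedom had a median of 15.8, against 7.10 in random lists matched on level and reads, above all 10000 lists. Peg10 and Sgce share their positions, and with these counted once the 16 regions had a median of 15.7, against 7.18, above 9999 of 10000 lists. Calls of the same read raise the chi-square where positions lie close together. With lists matched on level and on the number of positions, the 16 regions lay above 9999 of 10000 lists as well. For some region, however, only 3 gene ends were there to draw from. These lists were not matched on how far calls of the same read go together, which was not measured. Whether the columns differ more at imprinted gene ends is therefore not decided by the chi-square. The range over columns had a median of 21.0 percentage points for the 16 regions, and no matched random value is given for it. For 15 germline genes in the same interval the median was 9.59, at percentile 81.9 of lists with a median of 7.88 and at percentile 94.1 when matched on positions, and the range 11.9 points. The group of each column is not known, so the part of this spread that lies between control and arsenic was not measured.

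The mean autosomal level of library columns 1 to 10 was 42.7, 41.2, 41.0, 41.1, 40.7, 40.2, 40.1, 40.1, 42.1 and 42.0%. The highest and the lowest column differed by 2.68 points. Incomplete bisulfite conversion would raise unmethylated positions most, but at positions under 5% in the other columns the 2 columns differed by only 0.106 points, which argues against it. Read depth cannot be told apart from other causes. Over 10 columns, Spearman's rho of the level with log depth was -0.0667 (two-sided permutation p = 0.865) and Pearson's r was -0.00881 (two-sided permutation p = 0.981), with an adjusted p of 0.981 for both by Benjamini-Hochberg. Without the 2 columns farthest from the median depth r was -0.67, and for this reason the relation is left open. That value was given weight only after the result was seen: by the rule as first set, a rho under 0.6 in size, depth would be argued against. A difference between the control and arsenic groups is not excluded.

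Coverage was unevenly spread over positions. The 2137 most covered positions, 0.1% of all, took from 5.80% to 8.79% of a column's summed coverage, and the most covered position, on chromosome 2 at 98662677, held 6606680 reads over the 10 columns at a level of 66.4%. The next most covered positions lay close by, up to 98666504. Whether these reads come from a unique place in the genome was not tested, so the level need not be that of a single locus.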
